A study of Mus musculus with 226 samples.

How the data were processed

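Both deposited tables were used: a table of counts and a table of normalized values, each with every cell. The unit of the first is counts on genes, which the deposited values bear out, being whole numbers. The table has 24584 entries: 24491 genes, 92 spike-in controls and the TdTomato reporter. The unit of the normalized values was not given by the authors and was found to be the natural log of CPM + 1 over all entries of the deposited counts, with a highest value of 11.8. That table holds 15746 genes, and none of the 8745 genes left out of it had more than 445 counts over all cells. Everything reported here was computed from the counts. The unit CPM was computed here from the deposited counts with the sum over genes, without spike-ins and reporter, as the total. Of the genes, 7266 had 0 counts in every cell. No pair of cells was identical, and the highest correlation between a pair was 0.875.

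Per the submitters' processing notes, Trimmomatic 0.33, STAR 2.4.0, featureCounts of Subread 1.4.6, edgeR 3.14.0 and Seurat 1.4.0.12 were used with genome build mm10. Which tool made which table, the annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Gene positions and exon overlaps came from GENCODE M21 for the same assembly, and 23582 genes were matched by symbol. Cyr61 was not matched, so its overlaps are unknown. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, with random seed 1.

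The comparisons, groups, markers, 30 gene lists, size limits and most other settings were fixed from the labels before the data were examined. Each sample is 1 cell and no animal or preparation is named, so there are no replicates, and no p-value or standard error between groups is given. Counts were summed over the cells of a group and given as CPM with exact Poisson intervals at 95%. Shares of cells were given with exact Clopper-Pearson intervals at 95%. Log2 folds were taken on CPM with 1 CPM added to both groups. Where a group had 0 counts, the fold was computed against 3 counts over that group. Such a fold, given as at least so large, is a bound for the counted reads of those cells only.

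A gene was named when it met all of these limits. It had at least 10 CPM in the higher group and a count in at least 25% of that group's cells in the main set. Its log2 fold was at least 1 in size in the main set and at least 0.5 on the same side in the repeat set. Its difference of mean log2(CPM + 1) over cells was at least 0.5 on the same side in both sets. The 12 largest per side by the mean of both log2 folds were named, and beyond these the members of the gene lists that met the limits, the markers and Slc17a8. Some genes are not reported here. Inside a class, the 5 largest per side with at least 50 CPM, a count in at least 50% of cells and a log2 fold of at least 1 were named, for groups of at least 8 cells. Genes of the sex chromosomes used for sexing were kept apart. Gene lists were described by the median log2 fold of their members, if at least 5 were measured, with its percentile among 10000 random lists matched on expression.

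The limits were tried on simulated counts for the genotype comparison. Every count was drawn anew from the gene's mean and spread over Wildtype Middle cells, independently for each gene and cell, and known changes were added. Of 50 genes each, 43 were found for a log2 change of 2 and 47 for -2, but 10 for a change of 1 and 21 for -1, so the limits miss most differences near their own size. Of 8494 simulated unchanged genes, 28 met the limits. The simulation held no differences shared by the cells of an animal, day or preparation, so this number does not carry over to the measured cells.

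Cells were clustered on the natural log of CPM + 1 of the 2000 most variable genes with counts in at least 5 cells. The markers and the mitochondrially encoded genes were left out. The steps used 10 principal components, 10 neighbours and Leiden clustering at resolution 1. This gave 10 clusters. The rule that names them was set after the data had been seen: a cluster took the class with the largest share of its markers above the mean of the cluster means, and a tie or fewer than 3 such markers left it unnamed. Cells were matched to a Wildtype class by their correlation with the class mean profiles over up to 60 genes per class. Marker shares used a limit of 100 CPM, with 10 and 1000 CPM as alternatives. Cells had been picked by hand, so no caller for doublets was run, and no cell was left out.

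Alternative settings fixed beforehand and those added later are described with the settings that moved a result. Added after the data had been seen were cells thinned to 500000 counts, clusterings without chosen genes, other numbers of matching genes, cells with Xist only, P27 cells with a spike-in share below 2%, cells matched to the Ia-like profile, clusters of Wildtype cells made without any list gene, and the activity list within a class or between other pairs of places.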

Results

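RNA was measured by Smart-seq2, a full-length method for single cells, in spiral ganglion neurons, the neurons that carry sound information from the cochlear hair cells to the brain. The neurons were picked by hand for the red reporter tdTomato, which a bhlhb5::cre driver had switched on, at postnatal days 25 to 27. The cells came from Wildtype mice and from Vglut3-/- mice, which lack the vesicular glutamate transporter that inner hair cells use to release glutamate. The Wildtype cells were labelled by tonotopic location as Apex (56 cells), Middle (88 cells) or Base (42 cells), and all 40 Vglut3-/- cells were from the Middle. By age, the Vglut3-/- cells were 11 at P25, 4 at P26 and 25 at P27, and the Wildtype Middle cells were 2, 52 and 34. Apex cells were from P26 (12) and P27 (44), and Base cells from P25 (1) and P26 (41).

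Between 604006 and 5284683 counts on genes were present per cell, and a median of 8265.5 genes had a count. Median depth was 2.57e+06 counts in Vglut3-/- cells and 2.61e+06 in Wildtype cells, with medians of 7944 and 8341 genes. The P27 Wildtype Middle cells fell into a pair of sets by the share of counts on spike-in controls, 15 cells at 0.561 to 1.18%, like the Vglut3-/- cells of that day, and 19 cells at 2.79 to 10.1%. No label names the animal of a cell, so cells were not treated as replicates and no test between groups was made. Each group is described by its summed counts, scaled to the total on genes (CPM), with an exact Poisson 95% interval, or by a share of cells with an exact Clopper-Pearson 95% interval. Reads carry no molecular identifiers, so these intervals and the limits given for counts of 0 cover counting error only, not differences between animals or preparations. Transcripts of Xist and of the Y chromosome, counted as present above 7 CPM, set a lowest number of animals: at least 5 Vglut3-/- and 4 Wildtype mice over all ages. For the P27 Middle cells alone the lowest numbers were 2 Vglut3-/- mice and 1 Wildtype mouse. At P27 all 75 sexed Wildtype cells had Xist, while 16 Vglut3-/- cells had Xist and 9 had Y-linked transcripts.

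Slc17a8, which encodes VGLUT3 (chromosome 10, 89574020 to 89621253, minus strand, mm10), had 0 counts in every cell of both genotypes. Taking 3 cells as the limit that 0 leaves open, rather than the exact interval used for other shares, up to 1.61% of Wildtype and 7.5% of Vglut3-/- cells could still have had a count. The summed depth set limits of 0.00602 CPM in Wildtype and 0.0297 CPM in Vglut3-/- cells. The targeted gene was therefore not detectable at this depth in neurons of either genotype, and it checks nothing about the genotype labels.

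The first question was which neuron classes were present among the Wildtype cells. Spiral ganglion neurons comprise type I neurons, which contact inner hair cells and fall into Ia, Ib and Ic classes, and type II neurons, which contact outer hair cells. The Wildtype cells separated into groups that matched all of these classes, marked by the calcium buffers Calb2 and Calb1, the GPI-anchored protein Lypd1 and the catecholamine enzyme Th. Clusters were made without the marker genes, which were then used only to name them. By class, 63 Wildtype cells were Ia-like (33.9%, 27.1 to 41.2%), 73 were Ib-like (39.2%, 32.2 to 46.7%), 43 were Ic-like (23.1%, 17.3 to 29.8%) and 7 were type II-like (3.76%, 1.53 to 7.60%).

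Ia-like neurons had the most Calb2, at 10648 CPM, against 2235 CPM in Ib-like and 289 CPM in Ic-like neurons. The mean over the 63 Ia-like cells was 13.31 ± 0.56 on the log2 scale (SD over cells). The protocadherin Pcdh20 was at 142 CPM in Ia-like neurons, 9.82 CPM in Ib-like and 8.75 CPM in Ic-like neurons, but also at 252 CPM in type II-like neurons. Rxrg, a retinoid receptor, was at 67.2 CPM in Ia-like and 8.69 CPM in Ib-like neurons. Calb1 and Ttn were highest in Ib-like neurons, at 236 and 261 CPM, against 15.4 and 8.43 CPM in Ia-like neurons. Lypd1 was at 3732 CPM in Ic-like neurons, 53.0 CPM in Ib-like and 0.994 CPM in Ia-like neurons. The transcription factor Pou4f1 was graded across the classes, at 8.02, 150.7 and 1062 CPM in Ia-, Ib- and Ic-like neurons, and Runx1 was similar in Ib-like and Ic-like neurons (126.3 and 133.6 CPM). Grm8, a metabotropic glutamate receptor, was at 140 CPM in Ic-like and at or below 3.08 CPM in Ia- and Ib-like neurons.

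Type II-like neurons expressed Th at 2435 CPM, with a count in 5 of the 7 cells, while the type I-like classes had at most 0.0248 CPM. The neurotrophin receptor Ngfr and the transcription factor Gata3 were at 2654 and 5045 CPM in type II-like neurons, above 235 and 303 CPM in Ia-like neurons. Prph, the classical type II marker, had counts in 1 of the 7 cells. Cacng5 and Trim54, listed beforehand for Ia and Ib, did not follow their class: Cacng5 was highest in type II-like neurons (792 CPM) and Trim54 in Ia-like neurons (35.2 CPM against 4.29 CPM in Ib-like). The glial genes Sox10 and Fabp7 had 0 counts in every Wildtype class and Apoe reached at most 5.36 CPM.

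**Figure D1:**
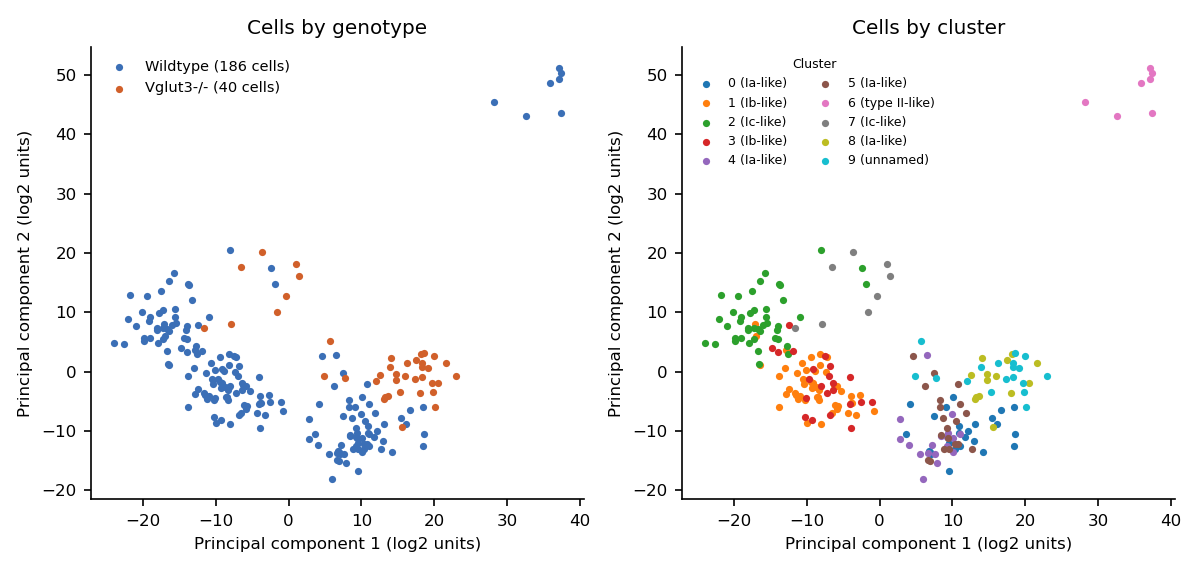
Each point is 1 neuron, placed by the first and second principal component of the clustering genes (PC1 and PC2, 5.37% and 3.86% of the variance). Points are coloured by genotype on the left and by cluster on the right. The components were computed on the natural log of CPM + 1, although the axes read log2 units. The 40 Vglut3-/- cells lie in clusters 7, 8 and 9, which hold no Wildtype cell.

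The main comparison asked what loss of VGLUT3, and with it of glutamate release from inner hair cells, does to the identity of Middle neurons. Vglut3-/- neurons grouped with each other rather than with Wildtype neurons of the same location. By their profile over class genes, most of them were nearest to the Ia-like class and few to the Ib-like class. Cells with high Ttn, Lypd1 or Pou4f1 were scarce, as were cells with high Pcdh20, an Ia marker. All 40 lay in 3 clusters without a Wildtype cell: 1 cluster of 8 was Ic-like, 1 of 14 was Ia-like and 1 of 18 met no class. Of the 10 nearest neighbours of a Vglut3-/- cell, 89.75% on average were Vglut3-/-, although such cells were 17.7% of all cells. For Wildtype Middle cells that share was 0.568%. Among the P25 and P26 cells alone, 46% of the neighbours of Vglut3-/- cells were Vglut3-/-, against 12.2% of cells, and none of the 15 lay in a cluster of their own. With 6 or 20 principal components in place of 10, clusters without a Wildtype cell held 37.5% or 25% of Vglut3-/- cells, so the neighbour share is the firmer measure.

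Every cell was also matched to the Wildtype class whose mean profile over 230 class genes it correlated with best. The markers were not among these genes, and 96.8% of Wildtype cells, from which the profiles were made, matched their own class. In the Middle, 29 of 40 Vglut3-/- cells (72.5%, 56.1 to 85.4%) matched the Ia-like profile, against 29 of 88 Wildtype cells (32.95%, 23.3 to 43.8%). Ib-like matches were 2 of 40 (5%, 0.611 to 16.9%) against 36 of 88 (40.9%, 30.5 to 51.9%), which rested on P27 (0 of 25 against 20 of 34), since at P25 and P26 the intervals overlapped (2 of 15 against 16 of 54). Type II-like matches were 2 of 40 (0.611 to 16.9%) and 0 of 88 (0 to 4.11%). Ic-like matches were 7 of 40 (17.5%, 7.34 to 32.8%) against 23 of 88 (26.1%, 17.3 to 36.6%), with overlapping intervals. The Ia-like excess was large at P27, at 20 of 25 (80%, 59.3 to 93.2%) against 4 of 34 cells (11.76%, 3.30 to 27.5%). At P25 and P26 it was 9 of 15 (60%, 32.3 to 83.7%) against 25 of 54 (46.3%, 32.6 to 60.4%), where the intervals overlapped. Vglut3-/- cells matched to Ia had a median correlation of 0.383 with the Ia-like profile, against 0.597 for Ia-like Wildtype cells. The latter had themselves made the profile, which favours them, so how much looser the Vglut3-/- match was is uncertain. Of the 40 Vglut3-/- cells, 16 had another class within 0.1.

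Single markers showed which features of the classes differed. Ttn reached 100 CPM in 0 of 40 Vglut3-/- cells (0 to 8.81%) and in 27 of 88 Wildtype Middle cells (30.7%, 21.3 to 41.4%). Lypd1 did so in 3 of 40 (7.5%, 1.57 to 20.4%) against 25 of 88 cells (28.4%, 19.3 to 39.02%), with intervals that just overlapped. For Pou4f1 the shares were 6 of 40 (15%, 5.71 to 29.8%) and 40 of 88 (45.5%, 34.8 to 56.4%), and for Runx1 6 of 40 and 37 of 88 (42.05%, 31.6 to 53.0%). The Pou4f1 and Runx1 intervals were apart at P27, at 2 of 25 against 20 of 34 cells and 1 of 25 against 15 of 34 cells. At P25 and P26 they overlapped, at 4 of 15 against 20 of 54 and 5 of 15 against 22 of 54 cells. Another Ib marker, Lrrc52, was at most at 3.76 CPM in a Vglut3-/- cluster, against 22.3 and 23.4 CPM in the Ib-like clusters. Calb1, also an Ib marker, was present in similar shares, 14 of 40 (35%, 20.6 to 51.7%) and 28 of 88 (31.8%, 22.3 to 42.6%). Calb2 was at or above 100 CPM in all 40 Vglut3-/- cells and in 75 of 88 Wildtype cells (85.2%, 76.1 to 91.9%). All 73 Wildtype Ib-like cells also reached that level, so this share does not set Ia apart from Ib. The Ia marker Pcdh20 was less frequent: 1 of 40 Vglut3-/- cells (2.5%, 0.0633 to 13.2%) against 20 of 88 (22.7%, 14.5 to 32.9%). The match to Ia was therefore not borne out by this marker.

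Within the Vglut3-/- cells Pou4f1, Lypd1 and Runx1 lay mainly in the small Ic-like cluster, which these markers had helped to name, while Calb1 was also found elsewhere. Of its 8 cells, 6 had Pou4f1, 6 had Calb1, 5 had Runx1 and 3 had Lypd1 at or above 100 CPM. In the other 32 cells, none had Pou4f1 or Lypd1, 1 had Runx1 and 8 had Calb1 at that level.

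**Figure D2:**
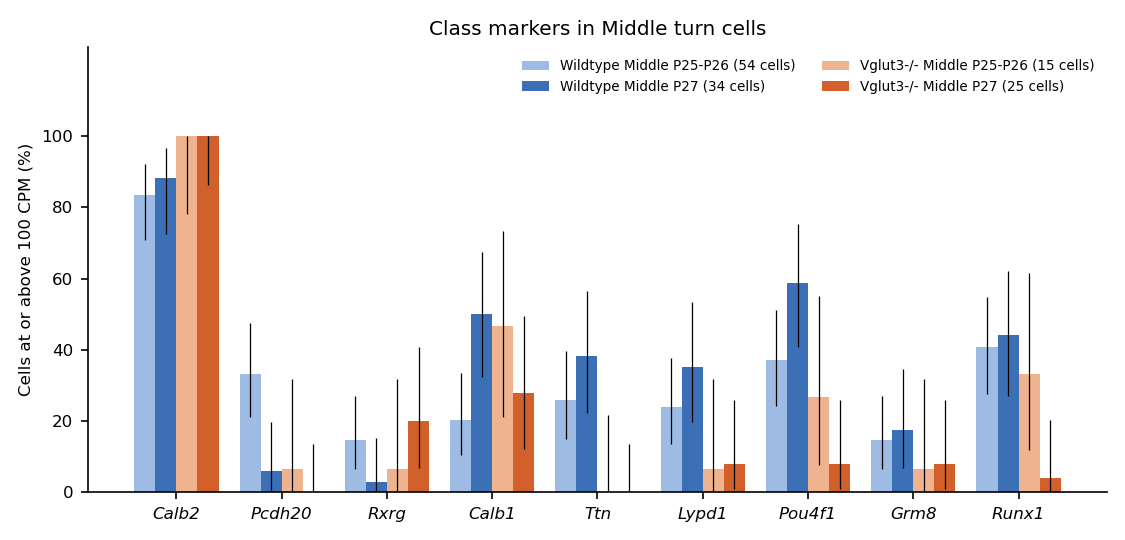
Bars give the percent of Middle cells at or above 100 CPM for 9 type I markers, in Wildtype cells of P25 and P26 (54 cells) and P27 (34), and Vglut3-/- cells of P25 and P26 (15) and P27 (25), with exact 95% binomial intervals. Ttn is at 0% in both Vglut3-/- sets, against 25.9% and 38.2% in the Wildtype sets, while Calb2 is at 100% in both Vglut3-/- sets.

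Gene expression was then compared between genotypes, with the P27 Middle cells (25 Vglut3-/- and 34 Wildtype) as the main set. The P25 and P26 cells (15 and 54), which are from other mice, served as a repeat. Ages were not matched in the repeat: Vglut3-/- cells were 11 at P25 and 4 at P26, Wildtype cells 2 and 52. Genotype and day can therefore hardly be told apart in it, here and in the shares above. In Vglut3-/- neurons several transcripts found in most Wildtype neurons were low or had no counts: the vesicle protein Sv2c was lower, and the potassium channel partner Kcnip3 and, at P27, the guidance cue Sema3d were not counted. They carried others that Wildtype neurons hardly had, such as Marcksl1, a MARCKS-like regulator of actin, St8sia2, which adds polysialic acid, and Necab1, a neuronal calcium-binding protein. Of 8835 genes above the minimum level, 411 met the size limits in both sets, 46.7% of them higher in Vglut3-/- cells (40.4% with TMM and 40.1% with median-ratio scaling). At P27 alone 997 genes met them, and 74 of these went the other way in the repeat set. Across genes, which are not independent replicates, log2 folds in both sets correlated at 0.38. Size alone was not specific to genotype: 895 genes met the same limits between Vglut3-/- cells of P27 and of P25 and P26, and 313 between Wildtype Middle cells of P27 and P26. Even within the P27 Wildtype Middle cells, 738 did between the sets of low and high spike-in share, against 1170 between Vglut3-/- and Wildtype cells of low share (24 and 15 cells). In this last comparison the log2 fold was 4.21 for Marcksl1, 4.56 for St8sia2, -3.57 for Sv2c and -5.64 for Ttn, but under 1 for Rps19 (0.83), Ebf3 (0.83), Cdh23 (0.89) and Timp3 (0.76), and Gpr37 was at 2.52 against low-share and 5.01 against high-share Wildtype cells.

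Marcksl1 (chromosome 4, 129513581 to 129515985, plus strand) was at 98.7 CPM (96.3 to 101.1) in Vglut3-/- and 2.22 CPM (1.93 to 2.55) in Wildtype cells at P27, a log2 fold of 4.95, with a count in 25 of 25 and 9 of 34 cells. In the repeat set it was at 138.5 and 5.29 CPM (4.47). St8sia2 (chromosome 7, 73939119 to 74013690, minus strand) was at 23.8 (22.6 to 24.9) and 0.345 CPM (0.234 to 0.489), a log2 fold of 4.20, and of 4.23 in the repeat. Necab1 had 29.3 CPM in Vglut3-/- cells at P27 and 0 counts in the 34 Wildtype cells, at least 879-fold higher against a limit of 3 counts over the group, and a log2 fold of 3.50 in the repeat. Ush1c, the scaffold protein harmonin, was at 57.8 CPM in 24 of 25 Vglut3-/- cells and had 0 counts in Wildtype cells at P27, at least 1732-fold higher. In the repeat set Ush1c was at 44.1 and 23.9 CPM (0.86), since 27 of 54 younger Wildtype cells had it. Folds given as at least so large are therefore no lower bounds for other cells or mice. Also among the 12 highest were A830018L16Rik, Plpp3, Padi2, Mpp3, Il1r1, Gpr37 and Fut9. Their log2 folds at P27 ran from 3.07 for Plpp3 to 4.51 for Padi2, with 4.26 for A830018L16Rik, and in the repeat from 2.53 for Padi2 to 4.18 for Plpp3. Il1r1 rested on 2 of 15 Vglut3-/- cells in the repeat set.

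Sv2c (chromosome 13, 95954594 to 96132577, minus strand) was at 5.11 CPM (4.59 to 5.68) in Vglut3-/- and 72.6 CPM (70.8 to 74.4) in Wildtype cells at P27, a log2 fold of -3.59. It had a count in 10 of 25 Vglut3-/- and in all 34 Wildtype cells, and the repeat gave 5.43 and 73.8 CPM (-3.54). Kcnip3 (chromosome 2, 127456498 to 127522094, minus strand) had 0 counts in all 40 Vglut3-/- Middle cells. Wildtype cells had it at 22.7 CPM in 26 of 34 cells at P27 and at 19.3 CPM in 33 of 54 younger cells, so it was at least 511-fold and 214-fold lower. Cfap161 was also at 0 in both Vglut3-/- sets, against 26.6 and 21.6 CPM, at least 599-fold and 239.8-fold lower. Sema3d was at 0 in Vglut3-/- cells and at 46.4 CPM in Wildtype cells at P27, at least 1044-fold lower, with a log2 fold of -3.27 in the repeat. Ttn (chromosome 2, 76703980 to 76982547, minus strand) was at 0.252 CPM (0.147 to 0.403) and 127.9 CPM (125.5 to 130.2) at P27, a log2 fold of -6.69, and of -6.49 in the repeat. Lypd1 was at 9.13 and 846 CPM at P27 (-6.39) and at 78.7 and 1012 CPM in the repeat (-3.67). Of the other lowest genes, Lhfp had 1 count at P27 against 61.5 CPM in Wildtype cells, Rab37 had 0 counts against 12.9 CPM, and Cd55, Fam184b, Nrip3 and Zfp712 had log2 folds of -4.52, -3.73, -2.58 and -2.17. Whether counting used the strand is not stated, and Necab1, Ush1c, Padi2, Ttn, Lypd1, Lhfp, Fam184b, Zfp712 and Cd55 overlap exons of a gene on the other strand, so their values are uncertain. The same holds for Runx1, Gata3 and Trim54 among the markers and for Nlgn1, Kcnab1, Gadd45a, Ebf3, Timp3, Cradd, Fdft1 and Syt4, which are described below.

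**Figure D3:**
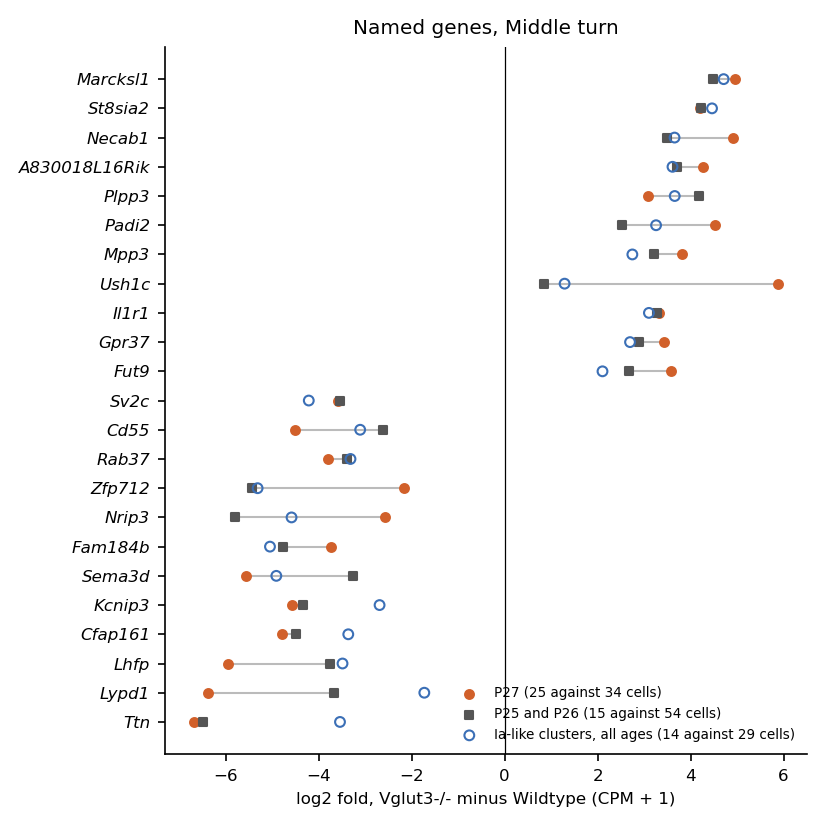
Log2 fold of Vglut3-/- over Wildtype Middle cells, computed on CPM + 1, for genes among the 12 highest and the 12 lowest by the rule, as circles at P27 (25 and 34 cells), squares at P25 and P26 (15 and 54 cells) and open circles within the Ia-like clusters of all ages (14 and 29 cells). The rule fixes the side in both age sets, and at P27 Marcksl1 is at 4.95, Ush1c at 5.88 and Ttn at -6.69.

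Of the members of gene lists chosen before the data were examined, 28 met the size limits, a small part of most lists: 4 of 26 measured synaptic vesicle and release genes, 2 of 20 potassium channel genes, 3 of 39 guidance and adhesion genes and 3 of 31 transcription factors. These members are therefore single genes and do not stand for their lists. Among transmitter and synaptic genes, Slc17a6, the vesicular glutamate transporter VGLUT2, was at 58.8 and 445 CPM at P27 (-2.90) and 146 and 325 CPM in the repeat (-1.15). Glrb, the glycine receptor beta subunit, was at 313 and 721 CPM (-1.20), then 369 and 749 CPM (-1.02), and the kainate receptor gene Grik4 was at 15.0 and 39.2 CPM (-1.33), but not lower in cells matched to Ia (0.21). Vamp2 and Syt4 were higher, with log2 folds of 1.11 and 1.68 at P27 and 1.41 and 0.54 in the repeat. Among channels, Kcnab1 was lower (-2.92 and -0.97) and the N-type calcium channel gene Cacna1b higher (2.17 and 0.93). Among transcription factors, Pou4f1 was at 15.0 and 341 CPM at P27 (-4.42) but only slightly apart in the repeat, at 196.6 and 288 CPM (-0.55), while Etv5 was higher (2.96 and 1.05), as was Ebf3 (1.21 and 0.53). For guidance and adhesion, Sema3e and Nlgn1 were lower (-1.85 and -1.77 at P27) and the netrin receptor gene Unc5d higher (490.1 and 184.8 CPM at P27). Espn and Cdh23, known from hair cell bundles, were higher, with log2 folds of 1.44 and 1.27 at P27 and 1.97 and 0.99 in the repeat. The activity-regulated genes Arc, Nr4a1 and Gadd45b were lower at P27 (-2.56, -2.44 and -1.88). They were 3 of 15 measured list members, of which 5 were above 0, such as Fos at 551 and 506 CPM. Vglut3-/- cells of P25 had Arc, Nr4a1 and Gadd45b at 9.15, 13.3 and 14.7 CPM. P26 Wildtype Middle cells had them at 26.4, 17.8 and 14.5 CPM. Here the differences were smaller for Arc and Nr4a1 and absent for Gadd45b, but the 4 P26 Vglut3-/- and 2 P25 Wildtype cells are left out. These genes were not lower inside each class, with 1.06 for Nr4a1 in the Ia-like clusters and 0.18 for Arc and 0.057 for Gadd45b in the Ic-like ones. Gadd45a and Stmn4 of the injury list were higher at P27 (1.79 and 1.52), but Stmn4 was not higher in the Ic-like clusters. Fdft1, Rps19, Cradd and Timp3 were higher (1.37, 1.16, 1.36 and 1.39) and Gng7 lower (-1.35), though not in the Ia-like clusters (0.54). Counting only the P27 cells with Xist (16 and 32), the log2 fold of Espn was 0.11, of Timp3 0.47, of Ebf3 0.67 and of A830018L16Rik 1.84.

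As whole lists, cytosolic ribosomal protein genes were higher in Vglut3-/- cells, with a median log2 fold of 0.51 at P27 (31 of 33 members above 0) and 0.40 in the repeat (32 of 35). Both medians lay at or above the 99.6th percentile of 10000 random lists matched on expression. The mitochondrially encoded genes had medians of -0.60 and -0.54, with 2 of 9 members above 0 in each set, at or below the 0.105th percentile. Shifts of these lists were not particular to genotype. Within Wildtype the ribosomal list was at -0.43 (P26 Apex against Base) and 0.30 (P27 Apex against Middle), the mitochondrial list at 0.41 and -0.36. All of these lay outside the range of random lists. Between genotypes, glutamate receptor genes had medians of -0.51 and -0.33 (1st and 3.1th percentile), voltage-gated calcium channel genes 0.33 and 0.81 (94.5th and 99.98th) and heat shock genes 0.26 in both sets (98.5th and 97.4th). Activity-regulated genes had medians of -0.22 and -0.21 (12.1th and 4.25th percentile), but of -0.68 (0.01th) with all ages together. Genes within 10 Mb of Slc17a8 had medians of -0.04 and 0.06. The other lists with at least 5 members measured in both sets had medians between -0.24, for sodium and HCN channels, and 0.28, for calcium-binding proteins, at P27. In the repeat set injury response genes had a median of 0.50 (96.7th percentile, against 0.07 at P27), pan-neuronal genes -0.21 (2.18th, against -0.04) and guidance and adhesion genes -0.17 (1.03th, against 0.08). Lists of glial, macrophage, blood, vessel, fibroblast, supporting cell and hair cell genes had too few measured members at P27 to be described, and no macrophage or erythrocyte gene reached the minimum level.

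Whether these differences went with the class makeup or were present inside a class was asked by comparing cells of like class. Of the 411 genes that met the size limits, 386 kept their side in the Ia-like clusters, 264 of them with a log2 fold of at least 1. In the Ic-like clusters 379 kept it, and 393 in cells matched to the Ia-like profile. The differences in Sv2c and Marcksl1 were of similar size inside the Ia-like class, while that in Slc17a6 was not. These cells are part of those from which the genes were chosen, so they are no independent repeat, and ages were mixed: the Ia-like Vglut3-/- cells were 4 at P25, 1 at P26 and 9 at P27, the Wildtype ones 1, 24 and 4. The Ia-like Vglut3-/- cluster (14 cells, cluster 8) was set against Ia-like Wildtype Middle cells (29 cells, clusters 0, 4 and 5), and the Ic-like cluster (8 cells, cluster 7) against Ic-like Wildtype Middle cells (20 cells, cluster 2). Inside the Ia-like class Marcksl1 was at 131 and 4.03 CPM (4.71), with a count in 14 of 14 and 5 of 29 cells, and Sv2c at 3.12 and 75.5 CPM (-4.22), in 5 of 14 and 29 of 29 cells. The other largest differences there were Bend4 (5.39), Cpne6 (5.32), Hells (4.35) and Kitl (3.69), higher in Vglut3-/- cells, and Nrip3 (-4.59), Car2 (-4.16), Me3 (-3.47) and Ccdc155 (-3.40), lower. The Ic-like Vglut3-/- cluster was mixed in its markers: Calb2, at 2139 CPM, was near the Ib-like level, and Calb1 was above the Ib-like level of 236 CPM. Grm8 was in 37.5% of cells against 90.7% in Wildtype Ic-like cells. Against the latter from the Middle, Calb1 was at 444 CPM in Vglut3-/- and 2.54 CPM in Wildtype cells (6.98) and Lypd1 at 160.3 and 4058 CPM (-4.65). There, Fgfr3, a listed supporting cell marker, was higher (5.77), as were Brinp3, Prkcd and Wls (4.15, 4.07 and 4.04), Fgf1 and Ldb3 lower (-5.42 and -4.55), and Sphkap and Dbpht2 were at 0 in the 8 Vglut3-/- cells, at least 1622-fold and 677-fold lower. By contrast Slc17a6 was similar inside the Ia-like class, at 10.8 and 12.1 CPM (-0.15), and higher in the Vglut3-/- cells matched to the Ia-like profile. In cells matched to the Ia-like profile (29 in each genotype), Cpne6, Marcksl1, Kcnip2 and Padi2 were among the highest (5.68, 4.60, 3.73 and 3.71). Nrip3, Sv2c, Car2, Ccdc155 and Cox8b were lowest there (-3.76, -3.55, -3.42, -3.01 and -2.98). Bend4, Me3, Fgfr3 and Brinp3 also overlap exons on the other strand.

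The second comparison asked how Wildtype neurons differ along the tonotopic axis, within P26 (Apex, Middle and Base) and within P27 (Apex and Middle), because no Base cell was from P27. All type I-like classes were present at each location. Of the 7 type II-like neurons, 6 came from the Apex, all at P27. Class shares differed between days at the Middle as well as between locations. At P26, 9 of 12 Apex cells were Ib-like (75%, 42.8 to 94.5%), against 16 of 52 Middle (30.8%, 18.7 to 45.1%) and 12 of 41 Base cells (29.3%, 16.1 to 45.5%). At P27 the order was the opposite, with 13 of 44 Apex (29.5%, 16.8 to 45.2%) and 23 of 34 Middle cells (67.6%, 49.5 to 82.6%) Ib-like. Ia-like cells were 24 of 52 at the P26 Middle (46.2%, 32.2 to 60.5%), 18 of 41 at the P26 Base (43.9%, 28.5 to 60.3%) and 1 of 12 at the P26 Apex (8.33%, 0.211 to 38.5%). At P27 they were 14 of 44 at the Apex (31.8%, 18.6 to 47.6%) and 4 of 34 at the Middle (11.76%, 3.30 to 27.5%). Type II-like cells were 6 of 44 at the P27 Apex (13.6%, 5.17 to 27.4%) and 1 of 41 at the P26 Base (2.44%, 0.0617 to 12.9%). None of the 88 Middle cells was type II-like (0 to 4.11%). At P26, the only day compared at all locations, 0 of 12 Apex cells were type II-like (0 to 26.5%). At P27 the Apex interval overlapped that of the Middle (0 of 34, 0 to 10.3%), so an excess at the Apex within a day is open. The line between Ib-like and the other type I-like classes moved with the clustering: clustered without the P27 cells, 33.3% of P26 Apex and 9.76% of P26 Base cells were Ib-like. The P27 Middle share was 35.3% at resolution 1.4 and 26.5% without activity, injury and heat shock genes, so the order of the locations at P27 is not firm.

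**Figure D4:**
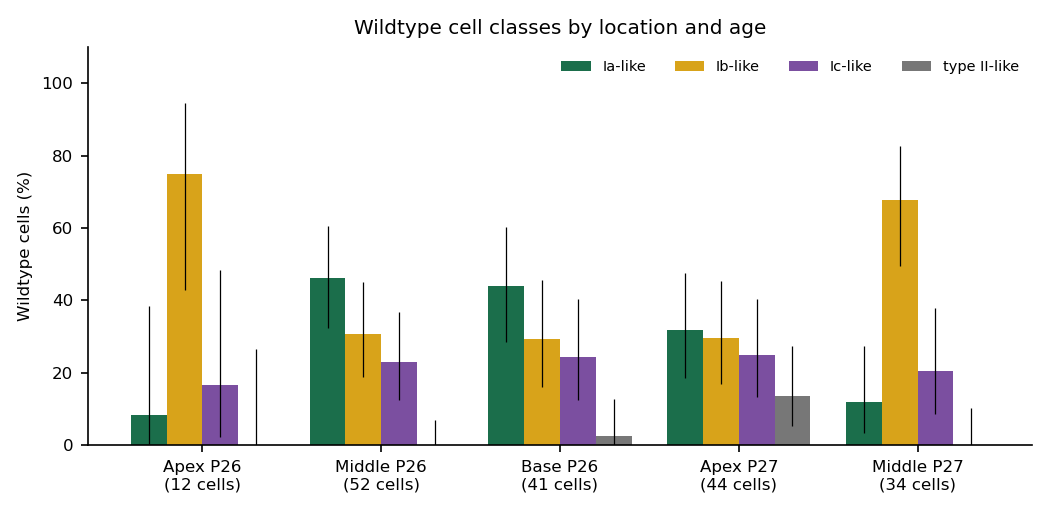
Bars give the percent of Wildtype cells in each class by location and age, with exact 95% binomial intervals. Ib-like cells are 75% at the P26 Apex and 29.5% at the P27 Apex, and 30.8% and 67.6% at the Middle of the same days, but other clusterings gave 33.3% for the P26 Apex and 26.5% for the P27 Middle.

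Gene expression along the axis was compared between Apex and Base at P26 (12 and 41 cells), with Apex against Middle at P27 (44 and 34 cells) as a repeat from other mice. In both sets the Apex cells had more of the potassium channel gene Kcns3, of the potassium channel partner Kcnip4 and of Opcml, a GPI-anchored adhesion protein. They had less of Kcnip2, of the latrophilin Adgrl2 and of the calcium release channel Ryr3. These genes were chosen for keeping their side in both sets. Of 8746 genes above the minimum level, 50 met the size limits in both sets as higher and 73 as lower at the Apex. At P26 alone 954 genes met them, 173 of which went the other way at P27, and the log2 folds of both sets correlated at -0.14 across genes. Another scaling would add 0.12 (TMM) or 0.13 (median ratio) to every log2 fold at P26, which leaves 48.1% or 49.6% of the genes within the limits higher.

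Opcml (chromosome 9, 27790775 to 28925410, plus strand) was at 183.7 CPM (179.6 to 187.9) at the Apex and 23.8 CPM (23.0 to 24.7) at the Base at P26, a log2 fold of 2.89, with a count in 12 of 12 and 12 of 41 cells. At P27 it was at 131 CPM at the Apex and 33.96 CPM at the Middle (1.92), in 43 of 44 and 20 of 34 cells. Kcns3 (chromosome 12, 11090202 to 11151056, minus strand) was at 93.1 (90.2 to 96.1) and 15.4 CPM (14.8 to 16.1) at P26 (2.52) and at 86.6 and 25.3 CPM at P27 (1.74). Kcnip4 was at 100.9 and 13.0 CPM (2.86), then 96.8 and 46.9 CPM (1.03), and the Ib marker Lrrc52 at 30.1 and 0.186 CPM (4.71), then 22.7 and 14.5 CPM (0.61). The other genes highest at the Apex were Nln, Rap2c, Mcf2, Myo10, Zkscan1, 4930563F08Rik, Ntng2 and Cwc22, with log2 folds from 3.00 for Nln to 1.21 for Cwc22 at P26. Adgrl2 (chromosome 3, 148815583 to 148990555, minus strand) was at 10.5 CPM (9.57 to 11.6) at the Apex and 103.9 CPM (102.1 to 105.6) at the Base (-3.18), and at 14.3 and 76.5 CPM at P27 (-2.34). Kcnip2 was at 56.8 and 175.8 CPM (-1.61), then 28.2 and 94.9 CPM (-1.72), and Ryr3 at 9.07 and 33.8 CPM (-1.79), then 3.33 and 33.2 CPM (-2.98). The P26 Apex cells had 0 counts of Gpm6a and Bend4, at least 475-fold and 171-fold lower than the Base, where 12 and 11 of 41 cells had them. Rasgrf1, Cit, Ehbp1l1, Fam196b, Cyr61, Zfp626, Efna1 and Mab21l2 were also among the 12 lowest, with log2 folds from -4.37 for Ehbp1l1 to -2.33 for Cyr61 at P26. Rasgrf1 rested on 3 of 34 Middle cells at P27. Between Apex and Middle at P26 the side turned for Zkscan1 (-0.31), Rasgrf1 (0.90) and AU041133 (-0.64). Further list members met the limits: Nlgn3, Matk, Btbd11 and Mvk were lower at the Apex (-1.12, -2.13, -1.11 and -1.84 at P26), and AU041133 and D10Wsu102e higher (1.10 and 1.01). Among Ib-like cells alone, P26 Apex against Base, the log2 folds were 6.83 for Kcnip4, 4.52 for Lrrc52, 3.79 for Opcml and 1.19 for Kcns3. Kcnip4, Adgrl2, Ryr3, Mab21l2, Bend4, 4930563F08Rik and D10Wsu102e overlap exons of a gene on the other strand, so their values are uncertain.

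As whole lists, most had opposite signs in the P26 and P27 comparisons. Activity-regulated genes had a median log2 fold of -0.98 at P26, where 4 of 18 members were above 0, and of 0.80 at P27, where 16 of 19 were. Injury response genes had medians of -0.86 and 0.70, ribosomal protein genes -0.43 and 0.30, mitochondrially encoded genes 0.41 and -0.36, and guidance and adhesion genes 0.16 and -0.16. Pan-neuronal genes were higher at the Apex at P26 (0.45, 12 of 16 members above 0) but not at P27 (-0.09), and cholesterol synthesis genes lower at P26 (-0.59) but not at P27 (0.17). Sodium and HCN channel genes had medians of 0.17 and 0.26 (89.1th and 98.5th percentile), and potassium channel genes of -0.19 and -0.16 (20.95th and 3.75th), inside the range of random lists except for the 0.26.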

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

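The tests on shares of cells matched to the Ia-like profile, on the spike-in share and on the activity list within classes and between other places were chosen only after the results were seen. Vglut3-/- cells formed clusters of their own, and with every cell thinned to 500000 counts 100% of them still did, with genes near Slc17a8 left out 100%, with activity, injury and heat shock genes left out 97.5%, and with genes of the X and Y chromosomes left out 100%. Since that measure is at its ceiling and depends on the clustering, the neighbour share counts more, and it was 89.5%, 89.5%, 91.75% and 90.75% in these settings, against 89.75% in the main one. With all ages together, sequencing depth and the left-out genes themselves are therefore excluded as the sole cause. Effects of activity, stress, sex or the linked region on other genes stayed in the clustering, so these tests cannot exclude them. Preparation could not be told apart: among P27 Middle cells of low spike-in share alone, 87.5% of Vglut3-/- cells lay in clusters of their own, between the limits set for either answer. For a batch that follows genotype, 313 genes met the main sizes between Wildtype Middle cells of P27 and P26, fewer than the 997 between genotypes at P27, but no label names a batch and 895 met them between Vglut3-/- cells of different days.

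More Vglut3-/- cells matched the Ia-like profile than Wildtype Middle cells did. Unequal ages cannot account for the excess at P27, where all cells were of the same age. There the lower bound of the Vglut3-/- share was 59.3% and the Wildtype upper bound 27.5%, which cover counting error only. The Wildtype share itself was 11.76% at P27 and 46.3% at P25 and P26, and differences between the animals or collections were not tested. At P25 and P26 the lower bound of the Vglut3-/- share was 32.3%, below the Wildtype upper bound of 60.4%, so there the excess itself is open. A turn other than the labelled one remains possible. With all ages together the upper bound of the Ia-like share at the Wildtype Base was 59.0%, which overlaps the Vglut3-/- interval of 56.1 to 85.4%. That bound was just below the lower bound of 59.3% for Vglut3-/- cells at P27, but no Base cell was from P27, so P27 cannot decide this.

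Activity-regulated genes stood out because their median log2 fold between the Apex and another location had opposite signs on both days, -0.98 against the Base at P26 and 0.80 against the Middle at P27, although the difference between these values was not tested. An animal or collection effect rather than place may account for it: against the Middle at P26 the median was -0.89, so with the same pair of places the sign still depended on the day. Among Ib-like cells the opposite signs remained, with medians of -0.76 at P26 and 0.49 at P27, each outside the range of random lists. Class makeup cannot be excluded by this, because activity genes took part in the clustering that named the class, and the Ib-like share moved without them. For the other classes the signs could not be compared, because the P26 Apex held a single Ia-like cell and 2 Ic-like cells.

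Injury response genes also had medians of opposite sign, -0.86 at P26 and 0.70 at P27, and this difference was not tested. The TdTomato reporter, which no comparison used, had a median of 525 CPM over all cells, and its untested group medians were 155.4 CPM at the P26 Base and 1039.9 CPM at the P27 Apex. The spike-in controls, which entered comparisons only through the split of P27 Middle cells by their share, took a median of 2.68% of counts per cell. Their untested group medians at P27 were 0.944% in Vglut3-/- and 3.09% in Wildtype Middle cells, the latter split into low and high cells. At the P26 Base the median was 0.799% and at the P27 Apex 4.48%.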

How the results depend on the processing

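Settings marked in the processing notes as added were chosen only after results were seen, among them the tests in Xist-only cells, in cells matched to Ia and between other pairs of places. No paired analysis was possible because each sample is 1 cell and the labels give no replicate numbers. Moved means outside the 95% interval of the value in the main setting, and the cause was not tested except where the setting itself is the cause.

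Clusters: Vglut3-/- cells in clusters of their own were 37.5% with 6 principal components, 25% with 20, 64% with P27 cells only and 0% with P25 and P26 cells only. Ib-like cells at the Wildtype P27 Middle were 35.3% at resolution 1.4 and 26.5% without activity, injury and heat shock genes. Without those genes Ib-like cells were 15.4% at the P26 Middle and 4.88% at the P26 Base. With a larger number of variable genes the P26 Base had 12.2% Ib-like and 41.5% Ic-like cells. With P25 and P26 cells only, Ib-like cells were 33.3% at the P26 Apex and 9.76% at the P26 Base, where Ic-like cells were 43.9% and type II-like cells 0%. The other 270 of 280 class shares stayed within their intervals. Wildtype Middle cells matched to Ia were 11.76% at P27 and 46.3% at P25 and P26.

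Marker limits, where the limit itself is the cause: at 10 CPM, Calb1 was present in 65% of Vglut3-/- and 48.9% of Wildtype Middle cells and Pou4f1 in 56.8% of Wildtype cells. At 1000 CPM, the Vglut3-/- shares were 2.5% for Calb1, 0% for Lypd1 and 2.5% for Pou4f1, and the Wildtype shares 71.6% for Calb2, 1.14% for Calb1 and 10.2% for Pou4f1. By age, Wildtype shares were 50% for Calb1 and 58.8% for Pou4f1 at P27, and 20.4% for Calb1 at P25 and P26.

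Size limits: with at least 50 CPM, 1.6e+02 genes (rounded) met them for genotype and 28 for location, and with 5 CPM added 77 did for location. With TMM or median-ratio scaling all 66 genotype folds stayed within their intervals.

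Signs: of 990 genotype folds 536 moved and 9 reversed, and of 371 location folds 275 moved and 7 reversed. Of list medians, 26 of 76 moved for genotype and 70 of 122 for location. In cells matched to Ia, log2 folds were 0.53 for Slc17a6, 0.21 for Grik4, 0.55 for Gng7 and 0.18 for Nr4a1. In the Ia-like clusters they were 0.54 for Gng7 and 1.06 for Nr4a1, and in the Ic-like clusters 0.057 for Gadd45b, -0.14 for Stmn4 and 0.18 for Arc. Between the P26 Middle and Base they were -0.23 for Myo10, -0.032 for 4930563F08Rik, -0.22 for Ntng2 and 0.50 for Fam196b. Between the P26 Apex and Middle they were -0.31 for Zkscan1, 0.90 for Rasgrf1 and -0.64 for AU041133. Without the cell that had most counts of the gene, 30 of 66 genotype folds moved and none reversed.

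Depth limits absence: 0 counts of Slc17a8 in 40 cells leave up to 7.5% of cells possible by the limit of 3 cells, and by the exact interval a class absent from the 12 P26 Apex cells could be up to 26.5%.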

Other observations

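The clusters used here were made from Wildtype cells without any gene of the lists, and these comparisons were chosen after the data had been seen, so the genes are examples chosen from the lists after their values were seen. Type II-like neurons (7 cells, against 179 others) had lower levels of several groups of neuronal genes than the other Wildtype neurons, and the 6 of them from the Apex also had high spike-in shares, up to 19.2% of counts. Pan-neuronal and type I genes had a median log2 fold of -1.89, potassium channel genes -1.95, sodium and HCN channel genes -1.28 and nuclear oxidative phosphorylation genes -0.97, while synaptic vesicle and release genes had -0.42 and glutamate receptor genes -0.10. Kcna1 was at 1.18 CPM in type II-like and 973 CPM in other neurons (-8.80). Sv2b was at 0 against 315 CPM and Syt2 at 0 against 180.9 CPM. Vamp1 was at 85.3 and 1033 CPM (-3.58), and Epha4 at 0.374 and 164 CPM (-6.91). Prox1 was at 4.67 and 100.4 CPM (-4.16).

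Type II-like neurons instead had Efna5 at 1842 CPM against 8.02 CPM (7.67), Gfra1 at 167.5 against 0.230 CPM (7.10) and Kcnc4 at 229 against 0.894 CPM (6.92). Grik3 was at 97.97 CPM in them and at 0.00207 CPM in the others. Necab1, which was higher in Vglut3-/- Middle neurons, was a type II-like gene in Wildtype cells, at 201 against 0.118 CPM. In type II-like neurons neuropeptide genes had a median of 2.496, injury response genes of 1.79, ribosomal protein genes of 1.06 and voltage-gated calcium channel genes of 0.97.

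Slc17a6 was at 72.01 CPM in Ia-like, 419.6 CPM in Ib-like, 631.6 CPM in Ic-like and 312 CPM in type II-like neurons. Against all other Wildtype neurons, Ic-like neurons had more Pcdh9 (144.8 and 6.79 CPM, 4.23), Kcnc2 (57.9 and 3.91 CPM, 3.59) and Cplx2 (57.4 and 4.84 CPM, 3.32). Ia-like neurons had less Ntng1 (11.9 and 244 CPM, -4.24) and Kcnip2 (27.3 and 124 CPM, -2.15), and their calcium-binding protein genes had a median of -0.48. Ebf1 was at 94.5 CPM in Ib-like neurons, below 221.5 CPM in Ia-like and 242.8 CPM in Ic-like neurons.

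Slc17a6 was lower in Vglut3-/- Middle neurons as a whole, with a log2 fold of -2.90 at P27. Inside the Ia-like clusters it was similar (-0.15), and in cells matched to the Ia-like profile it was higher in Vglut3-/- cells. Inside the Ia-like clusters activity-regulated genes had a median log2 fold of 0.68 in Vglut3-/- cells, inside the Ic-like clusters of -0.55, and in cells matched to the Ia-like profile of -0.06, so no side held throughout. In the same Ia-like clusters heat shock genes had a median of 0.44 and pan-neuronal genes of -0.35. Injury response genes, with 5 measured members, had 1.15 there, but -0.26 in the Ic-like clusters and 0.34, inside the random range, in cells matched to Ia. These comparisons mix ages, and between Wildtype Middle cells of P27 and P26 the activity list itself differed by -0.61.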
